A study of Mus musculus with 4 samples.

How the data were processed

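Droplet single-cell RNA sequencing of cells sorted from mouse hearts was used, with 4 libraries and 1 library per group. Each library pooled the hearts of 5 adult mice of mixed sex, per the series' design text. The sort kept CD64+ phagocytes of the heart (CD45+, CD11b+, Ly6G negative, Ly6C low), per the same text, and 10000 cells were loaded per group, per the labels' protocols. The sources differ on the reagent kit: the labels' protocols name version 3.1 of the 3' kit and, for the library steps, version 1, which the design text names too.

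The deposited matrices hold raw UMI counts per gene and cell barcode, without normalisation, for the barcodes that Cell Ranger kept. Cell Ranger 7.1.0 made them per the file headers, whereas the labels' protocols name version 3. Reads were aligned to the mm10 transcriptome per the labels' protocols; whether intronic reads were counted is not given in the sources used here. The authors worked in Seurat, version 3.2.3 per the labels' protocols and version 4 per the submitters' processing notes. Each matrix lists the same 32285 genes by Ensembl ID and symbol, of which 32158 IDs were found in the GENCODE mouse annotation of the same build, used for gene positions. UMIs remove PCR copies, so the counts are close to molecules, and all intervals given cover counting error only.

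Cells were kept by the filters the submitters state: a mitochondrial share under 10%, fewer than 30000 UMIs, and more than 500 and fewer than 7000 genes. This left 17312 of 27968 barcodes, in which 24650 genes were detected. The submitters state 38066 barcodes with 21681 genes before these filters and 17438 cells with 20290 genes after them. The difference in barcodes was not resolved. Kept cells held a median of 11848 UMIs and 3674 genes. Scrublet (scanpy 1.11.5) at its default threshold marked 49 cells, 0.283% of those kept, which is too few for a working call, so no doublets were removed in the results given first.

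Kept cells of the 4 libraries were normalised together with SCTransform (sctransform 0.4.2 in its original form, Seurat 5.3.0, R 4.3.3), reduced to 80 principal components and clustered by graph at resolution 0.6, the settings the submitters state, with no integration across libraries. The 23 clusters were named from 25 marker lists fixed before the data were examined, as were the filters, comparisons, gene lists, the rule for naming genes and the other settings to be tried; those added later are named where they are given. A marker counted for a cluster when its summed CPM, with 5 CPM added, was at least 2-fold above that of all other cells and more than 10% of the cluster's cells held a UMI. A cluster took a class name when at least 60% of a list's markers, and at least 3, counted, unless its 10 leading genes by fold held more markers of another class. Any other cluster was called macrophage-like when at least 7 of the 10 macrophage markers lay at 25% or more of their level over all cells, and took a subset name when at least 40% of that subset's markers counted. These thresholds were set after the data were seen. So was the rule that left clusters with macrophage markers without a name where their cells had a median under 50% of their libraries' median UMIs. Clusters with macrophage markers whose leading genes held more markers of another class were left without a name too. The share of all these clusters per library is given with the results. The classes are therefore rebuilt names and not the authors' annotation.

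UMIs were summed per library over all macrophage-like cells, leaving out the cycling cluster, and divided by the total to give a CPM value. A ratio of CPM between libraries carries an exact conditional binomial 95% interval, and a share of cells an exact Clopper-Pearson 95% interval. A count of 0 was read against a floor of 3 counts. Genes with a mean of at least 10 CPM over the 4 libraries were compared (8493 genes). For 18 gene lists, the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on expression, as a description of these libraries. Members at least 1.5-fold higher or lower were counted, and the median's counting range came from 200 Poisson resamples.

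Genes named for a contrast are the 12 with the highest and the 12 with the lowest CPM ratio among genes with a mean of at least 20 CPM. Sex-linked, mitochondrial and ribosomal protein genes, unnamed gene models and markers of cells other than phagocytes were not eligible, 252 genes together. Nor were a further 301 genes at more than 5 times the macrophage level in such a class, which left 5962. That screen used named classes only, so an unnamed cluster with T cell markers was not covered. For the difference between the carboplatin contrasts the rule takes 5 genes per direction, and for each list the 4 members with the largest absolute log2 ratio. A gene named outside this rule is said to be. Some genes that the rule takes are not reported here.

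Shares of cells with a UMI of 9 marker genes were compared after each cell was thinned to 2000 UMIs, with shallower cells left out. Endothelial-like cells served as the class taken to lack macrophage transcripts. Whether they express some of the 9 genes themselves was not tested, so their shares can exceed background. For the proliferation and cell cycle genes Mki67, Top2a and Cdkn1a their shares are not read as background. Cells with Xist UMIs and no Y-linked UMI (Ddx3y, Uty, Kdm5d, Eif2s3y) were called female, and cells with Y-linked UMIs and no Xist male. Ratios within each sex come from different mice of the same pools, but are not replicates, since the number of mice behind each is not given in the sources used here.

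The ratio and interval calculation was tested on simulated independent Poisson counts with 200 of 8493 genes changed. The intervals assume the same model, so this checks the calculation only, and not clumping of UMIs in cells or spread among mice. All 3-fold and 4-fold changes were recovered as at least 2-fold in each contrast, no unchanged gene was called, and intervals covered the true ratio for 95.3% of genes for carboplatin against PBS under saline, 94.8% for that contrast under AngII/PE, 95.5% for AngII/PE against saline after PBS and 95.5% after carboplatin. Alternatives were other cell filters, resolutions of 0.3 and 1.2, log-normalised values with 30 components and 2000 variable genes, clustering without the marker genes, single sexes, TMM factors (edgeR 4.0.16), expression minimums of 1 and 50 CPM, a pseudocount of 1 CPM, mean CPM of cells, other populations and cluster weights, and thinning to 1000 or 4000 UMIs. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.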

Results

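The series asked how a DNA-damaging chemotherapy changes the macrophages of the heart. Mice received carboplatin, a platinum compound that crosslinks DNA, at 45 mg/kg, or PBS, 2 times a week for 2 weeks. After 4 weeks of recovery a minipump delivered saline, or angiotensin II (1.5 mg/kg per day) with PE (50 mg/kg per day), for 7 days. Angiotensin II is a peptide hormone that constricts vessels, and the pair is called AngII/PE in what follows. Hearts of 5 mice per group were pooled into 1 library of sorted phagocytes. The files held 6910 barcodes for PBS with saline, 7049 for carboplatin with saline, 5997 for PBS with AngII/PE and 8012 for carboplatin with AngII/PE, and 65115918, 64604270, 62943457 and 95752612 UMIs in the same order. The filters kept 4310, 3484, 3849 and 5669 cells, or 62.4%, 49.4%, 64.2% and 70.8% of barcodes. The carboplatin saline library lost most to the mitochondrial limit, 43.2% of its barcodes against 31.1% for PBS with saline. With 1 library per group there is no replicate spread, so no difference was tested, no p-value is given, and each comparison is between libraries.

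Macrophage-like cells made up most of the named mononuclear phagocytes in each library, after a gate for CD64+, Ly6C low and Ly6G negative cells. Their share was 88.0% (95% interval 86.5 to 89.3) of 2203 phagocytes for PBS with saline, 81.5% (79.2 to 83.6) of 1243 for carboplatin with saline, 91.5% (90.3 to 92.6) of 2335 for PBS with AngII/PE and 94.2% (93.5 to 94.9) of 4150 for carboplatin with AngII/PE. Monocyte-like cells with markers of patrolling monocytes formed 1.86%, 4.51%, 0.128% and 0.0723%, 2.42 times (1.63 to 3.60) as large a share after carboplatin under saline. The AngII/PE libraries held 3 such cells each. The sort gate was on low Ly6C, so these are shares of sorted cells. Dendritic-cell-like cells formed 8.90%, 11.4%, 6.64% and 2.92%, so that the carboplatin to PBS ratio was 1.28 (1.05 to 1.58) under saline and 0.439 (0.348 to 0.554) under AngII/PE. The ratio under saline was 1.02 with log-normalised values and 1.02 with the unnamed clusters included, so no direction is read from it. Cycling cells formed 1.27%, 2.57%, 1.76% and 2.80%, a ratio of 2.03 (1.23 to 3.35) under saline and 1.59 (1.12 to 2.26) under AngII/PE. Under saline that ratio was 1.17 in female-called and 6.84 in male-called cells.

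The macrophage-like class was held by different clusters under saline and under AngII/PE. Under saline, the cluster with resident macrophage markers held 91.1% of macrophage-like cells after PBS and 82.5% after carboplatin, against 4.12% and 1.15% under AngII/PE. There the class was spread over a cluster without a subset name (27.9% after PBS and 37.2% after carboplatin), an MHC class II cluster (28.6% and 23.4%), an inflammatory cluster (26.6% and 26.1%), a lipid-associated cluster (8.99% and 7.39%) and an interferon cluster (3.79% and 4.83%). As a share of phagocytes, the resident-like cluster had a carboplatin to PBS ratio of 0.839 (0.803 to 0.877) under saline, also 0.839 when clustered without marker genes, but 0.537 at a resolution of 1.2 and 0.457 with log-normalised values. Under AngII/PE that ratio was 0.288 (0.202 to 0.411), from 45 and 88 cells, but 0.462 without the marker genes, 1.01 with a minimum of 1000 genes per cell and 1.30 with log-normalised values, so no direction is read from it. AngII/PE against saline gave 0.0470 (0.0383 to 0.0578) after PBS and 0.0161 (0.0120 to 0.0216) after carboplatin, and 0.0932 and 0.0514 without the marker genes, 0.102 and 0.121 with a minimum of 1000 genes per cell, and 0.153 and 0.435 with log-normalised values.

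Named phagocytes were 51.1%, 35.7%, 60.7% and 73.2% of the cells that passed the filters, in the order PBS saline, carboplatin saline, PBS AngII/PE and carboplatin AngII/PE. Clusters with macrophage markers that were left without a name, by thresholds set after the data were seen, held 27.7%, 33.7%, 24.1% and 16.4%. Endothelial-like cells held 13.9%, 15.9%, 7.90% and 6.26%, and B-like cells 3.16%, 5.54%, 1.92% and 0.759%, despite the sort. Fibroblast-like cells held 1.72%, 2.01%, 2.78% and 1.61%, cardiomyocyte-like cells 0.696%, 1.21%, 1.25% and 1.11%, mural-like cells 0.673%, 1.29%, 0.234% and 0.212%, and neutrophil-like cells 0.371%, 0.488%, 0.598% and 0.265%.

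Timd4, the phosphatidylserine receptor that marks long-lived tissue macrophages, was detected in 15.6% (14.1 to 17.3) of macrophage-like cells for PBS with saline and 0.989% (0.475 to 1.81) for carboplatin with saline at 2000 UMIs per cell. It was found in 0.424% and 0.0771% after PBS and after carboplatin under AngII/PE, the last being 3 of 3889 cells. Endothelial-like cells had 1.43% in the PBS saline library and 0 in the others, where 0 of 438, 283 and 320 cells allow shares of up to 0.685%, 1.06% and 0.938%. The AngII/PE shares of Timd4 lie under these limits, which only say what a count of 0 in few cells allows. Background was thus not measured there, and these shares were not told apart from it. The carboplatin saline share lies close to its limit. Cd163, the haemoglobin-haptoglobin scavenger receptor, was detected in 36.3% (34.2 to 38.5) after PBS and 5.93% (4.56 to 7.57) after carboplatin under saline, and in 6.93% and 3.86% under AngII/PE, against 3.06%, 0.685%, 0.353% and 0.312% of endothelial-like cells. Lyve1, a hyaluronan receptor, was found in 30.4% and 19.4% under saline and 2.83% and 2.96% under AngII/PE (endothelial-like 3.47%, 2.05%, 1.41% and 0.938%). Under AngII/PE the intervals of the macrophage-like and endothelial-like shares overlapped. Folr2, a folate receptor, was found in 35.2%, 28.6%, 8.72% and 14.5% (endothelial-like 5.10%, 2.05%, 0 and 2.81%).

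Ccr2, the chemokine receptor of monocyte-derived cells, went the other way under saline, from 13.4% (11.9 to 14.97) after PBS to 30.4% (27.5 to 33.3) after carboplatin, with 25.6% and 29.1% under AngII/PE (endothelial-like 1.84%, 2.28%, 1.06% and 2.19%). H2-Aa, an MHC class II chain, was found in 90.9%, 97.1%, 60.1% and 58.4%, with 29.2%, 34.9%, 21.6% and 22.5% of endothelial-like cells. The class leaves out the cycling cluster, which by itself keeps the proliferation genes Mki67 and Top2a low. Mki67 was found in 1.66%, 1.09%, 1.84% and 1.59% (endothelial-like 0.408%, 1.37%, 1.41% and 3.44%) and Top2a in 0.622%, 0.989%, 0.990% and 1.29% (endothelial-like 0.204%, 1.83%, 1.06% and 4.06%). The cell cycle inhibitor Cdkn1a was found in 30.98%, 31.2%, 27.4% and 28.2%, with overlapping intervals within each carboplatin comparison (endothelial-like 16.1%, 17.4%, 20.8% and 22.8%). Thinning left out 8, 2, 14 and 21 macrophage-like cells and 108, 116, 21 and 35 endothelial-like cells. Median depths were 13605, 16474, 14966 and 14067 UMIs in macrophage-like and 6958, 7865.5, 10415 and 11001 in endothelial-like cells. Without thinning, the macrophage-like shares were 43.3%, 3.55%, 2.34% and 0.179% for Timd4, 63.8%, 23.1%, 17.0% and 14.0% for Cd163, 48.8%, 35.5%, 6.04% and 7.70% for Lyve1, 60.5%, 53.6%, 24.0% and 35.1% for Folr2, and 23.5%, 52.3%, 52.3% and 54.4% for Ccr2. The corresponding values were 98.1%, 99.7%, 80.0% and 83.8% for H2-Aa, 6.04%, 8.79%, 7.91% and 9.13% for Mki67, 3.82%, 7.60%, 6.51% and 7.77% for Top2a, and 63.0%, 67.2%, 61.0% and 61.6% for Cdkn1a.

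**Figure D1:**
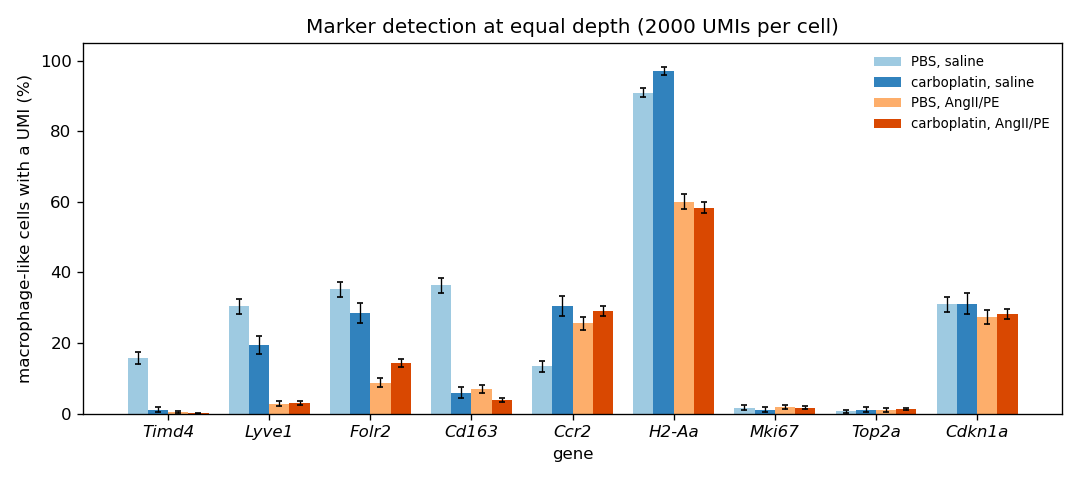
Percentage of macrophage-like cells with at least 1 UMI of each marker gene (x axis) after thinning to 2000 UMIs, 1 bar per library, with exact 95% intervals for counting error. Timd4 stands at 15.6% for PBS with saline and at or below 0.989% in the other libraries, with the AngII/PE shares not told apart from background. Ccr2 stands at 13.4% for PBS with saline and above 25% elsewhere.

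The first comparison asked how macrophages differed after carboplatin, 4 weeks of recovery and 7 days of a saline pump. Among the genes with the lowest ratios in the carboplatin library, Timd4 was 17.8-fold lower. This point estimate may be too small, since the share of cells with Timd4 there lay close to the limit of background. The scavenger lectin Colec12 was 9.13-fold lower (8.29 to 10.1), Cd163 8.60-fold (7.96 to 9.29) and the complement receptor Vsig4 3.50-fold (3.09 to 3.98). The chemokine gene Ccl24 was 2.79-fold lower (2.63 to 2.97). Higher in the carboplatin library were the TGF-beta family ligand Gdf3, 3.37-fold (2.98 to 3.82), the interferon-induced GTPase Gbp2, 2.37-fold (2.15 to 2.62), the T cell chemoattractant Ccl5, 2.24-fold (1.92 to 2.61), and Ccr2, 2.07-fold (1.99 to 2.16). The log2 ratio of Ccl5 was 0.29 in female-called and 3.32 in male-called cells, that of Gbp2 0.79 and 2.03, that of Colec12 -2.61 and -4.31 and that of Vsig4 -1.30 and -3.08. The resident-like cluster held 82.5% of these cells after carboplatin and 91.1% after PBS. Ccl5 was also a leading gene of an unnamed cluster with T cell markers, which the exclusion of genes of other cells did not cover. That cluster held 18 cells for PBS with saline and 35 for carboplatin with saline, so RNA from such cells stays open for Ccl5.

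Of the 8493 genes compared, 36 were at least 2-fold higher and 57 at least 2-fold lower in the carboplatin saline library, and all 36 and 54 of the 57 had the same direction in female- and male-called cells. Male-called cells alone gave 139 and 131. These genes were chosen from the sum of female and male cells, so their shared direction is partly built in. Across 8489 genes not chosen by fold, the female and male log2 ratios had r = 0.274 (Spearman's coefficient 0.014). The other genes named at the low end were Ppp1r9a (log2 ratio -2.24), the NAD hydrolase Cd38 (-1.94), the collagen prolyl hydroxylase P3h2 (-1.85), complement C4b (-1.50), the peptide transporter Slc15a2 (-1.41), the heparan sulphate sulphotransferase Hs3st3a1 (-1.30) and the recombination repair gene Rad51b (-1.25). Those at the high end were the potassium channel Kcnn4 (1.38), Dock5 (1.32), the oestrogen receptor Esr1 (1.17), Calhm6 (1.12), Abcg3 (1.09), the MHC class I gene H2-Q6 (1.07), the matrix elastase Mmp12 (1.04) and the non-coding RNA AW112010 (1.04). Among these, Timd4 lies on chromosome 11 (46810800 to 46844332, plus strand), Colec12 on chromosome 18 (9707595 to 9882644, plus), Cd163 on chromosome 6 (124304656 to 124330527, plus) and Gdf3 on chromosome 6 (122605403 to 122610087, minus) of mm10. All are protein coding.

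In the resident macrophage programme 10 of 14 measured genes were at least 1.5-fold lower and none higher (median -0.72), a median below those of all 10000 random lists. In MHC class II presentation 1 of 10 genes was at least 1.5-fold higher and the median was 0.40, above all random lists, with 0.23 in female- and 0.68 in male-called cells, led by the class II transactivator Ciita (0.68), H2-Ab1 (0.55) and H2-Eb1 (0.49). Alternative activation had 4 of 10 genes lower (-0.47) and iron and haem handling 4 of 14 (-0.38), including the iron exporter Slc40a1 (-1.06) and the prostaglandin dehydrogenase Hpgd (-1.002). Dissociation and immediate-early stress genes, a sign of handling, had a median of -0.30 over 33 genes, with Ccn1 at -4.09, but -0.01 in female-called cells against -0.46 in male-called cells. In the inflammatory cytokine list 5 of 28 genes were higher (median 0.10), among them Cxcl9 (0.99) and Cxcl10 (0.89), but the median was 0.19 in female- and -0.11 in male-called cells. In the type I interferon list 3 of 34 were higher (0.11), with Ifit2 at 0.86, and medians of -0.03 in female- and 0.41 in male-called cells. Markers of classical monocytes, 7 measured, had a median of -0.25, with Fn1 at -1.36, fibroblast markers, 3 measured, 0.35, cardiomyocyte markers, 7 measured, -0.19, and dendritic cell (cDC2) markers, 5 measured, 0.01. Sex-linked genes, 4 measured, had a median of 0.08.

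Lists tied to DNA damage stayed near 0 in this comparison. The p53 target and DNA damage list had 1 of 31 genes higher and none lower (median -0.03), with Sesn2 at 0.65 and Plk2 at -0.53, and Cdkn1a at -0.11. The senescence list had 2 of 21 higher and 2 lower (-0.02), with Mmp9 at -1.82 and Mmp12 at 1.04. The cGAS-STING list had none of 9 beyond 1.5-fold (0.10). The medians were 0.14 for S phase, -0.05 for G2/M, 0.15 for monocyte-derived genes, 0.01 for lipid-associated, 0.02 for phagocytosis, -0.06 for growth factor and -0.02 for glycolysis genes. In the phagocytosis and efferocytosis list 3 of 27 genes were higher and 2 lower.

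The second comparison asked the same of mice under AngII/PE, where the unnamed, MHC class II and inflammatory clusters held most of the class in both libraries. Timd4 had 7 UMIs after carboplatin and 128 after PBS, at shares of cells not told apart from background, so no fold is read from them. P3h2 was 4.62-fold lower (3.90 to 5.49), Vsig4 3.34-fold (2.86 to 3.91), Colec12 2.18-fold (1.95 to 2.43) and Cd163 2.09-fold (1.96 to 2.22). Folr2 was 1.83-fold higher (1.74 to 1.92), the class IIa histone deacetylase Hdac9 1.82-fold (1.77 to 1.87) and the monocyte chemokine Ccl7 1.55-fold (1.50 to 1.60). The largest ratio was that of the lectin Cd207, 34.9-fold higher (17.6 to 81.3). It is a ratio to 8 UMIs in 6 cells, for which no background was measured, and 415 of its 487 UMIs lay in 4 cells of the resident-like cluster, all female-called, with 361 in 1 of them. Male-called cells held 3 of its UMIs after carboplatin and 6 after PBS, too few to read a direction.

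Of the 8493 genes, 8 were at least 2-fold higher and 38 at least 2-fold lower in the carboplatin AngII/PE library, with the same direction in both sexes for 6 and 38. Across 8489 genes not chosen by fold, the female and male log2 ratios had r = 0.437 (Spearman's coefficient 0.284). The count of higher genes was 24 in female-called and 3 in male-called cells alone, and within the resident-like cluster, from 45 and 88 cells, 224 were higher and 438 lower. Low-end genes also included the calcium channel Cacna1a (-2.21), Hs3st3a1 (-1.57), the inflammasome gene Nlrp1b (-1.05), Celf4 (-1.002), Adam22 (-0.95), Rtn1 (-0.95) and Mmp12 (-0.85, but 0.42 in female-called cells). In female- and male-called cells, the values were -3.09 and -0.31 for Nlrp1b, -0.29 and -1.96 for Celf4, -0.56 and -2.51 for Cacna1a, -1.14 and -3.66 for Vsig4, and 1.33 and 0.22 for Folr2. At the high end were the resistin-like gene Retnla (2.31, from 95 and 11 UMIs, with no background measured), the clock output gene Dbp (0.90), the class I genes H2-Q7 (0.79) and H2-Q6 (0.72), the latter at -0.19 in male-called cells, Cmah (0.77), the platelet-derived growth factor Pdgfc (0.75), Reps2 (0.68) and the interferon-induced Ly6e (0.64). Cd207 lies on chromosome 6 (83671215 to 83677857, minus strand) and Retnla on chromosome 16 (48842551 to 48844461, plus).

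The type I interferon list had the highest median in this comparison, 0.25 over 34 genes, above all random lists, with Zbp1 at 0.58, Ifi27l2a at 0.51 and Bst2 at 0.51. Only 1 gene passed 1.5-fold, and the medians were lower within each sex, 0.07 in female- and 0.20 in male-called cells. Female-called cells were 29.2% of called macrophage-like cells after PBS and 49.4% after carboplatin, so the pooled median also holds this change of mix. The resident macrophage programme had 3 of 14 genes lower and 1 higher, with a median of 0.17, and 0.43 in female- and 0.05 in male-called cells. Its lower members were Vsig4, Cd163 and Timd4, the last between levels not told apart from background. MHC class II presentation had a median of -0.17 with no gene beyond 1.5-fold, and H2-Eb1 at -0.31. Inflammatory cytokines had a median of -0.16, with the prostaglandin synthase Ptgs2 at -0.71 and Il1rn at -0.58. Medians were 0.15 for monocyte-derived, 0.09 for cGAS-STING, 0.10 for p53 target, 0.04 for senescence, 0.06 for S phase, -0.01 for G2/M, -0.03 for alternative activation, -0.03 for lipid-associated, 0.02 for phagocytosis, 0.13 for growth factor, 0.10 for iron, 0.09 for glycolysis and 0.00 for immediate-early genes. The alternative activation median was 0.36 in female- and 0.00 in male-called cells, and senescence, immediate-early and fibroblast lists had opposite signs in them, 0.27 and -0.06, 0.12 and -0.11, and 0.21 and -0.04. Classical monocyte markers stood at 0.14, cDC2 markers at -0.20, cardiomyocyte markers at -0.10, fibroblast markers at 0.15 and sex-linked genes at -0.42.

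**Figure D2:**
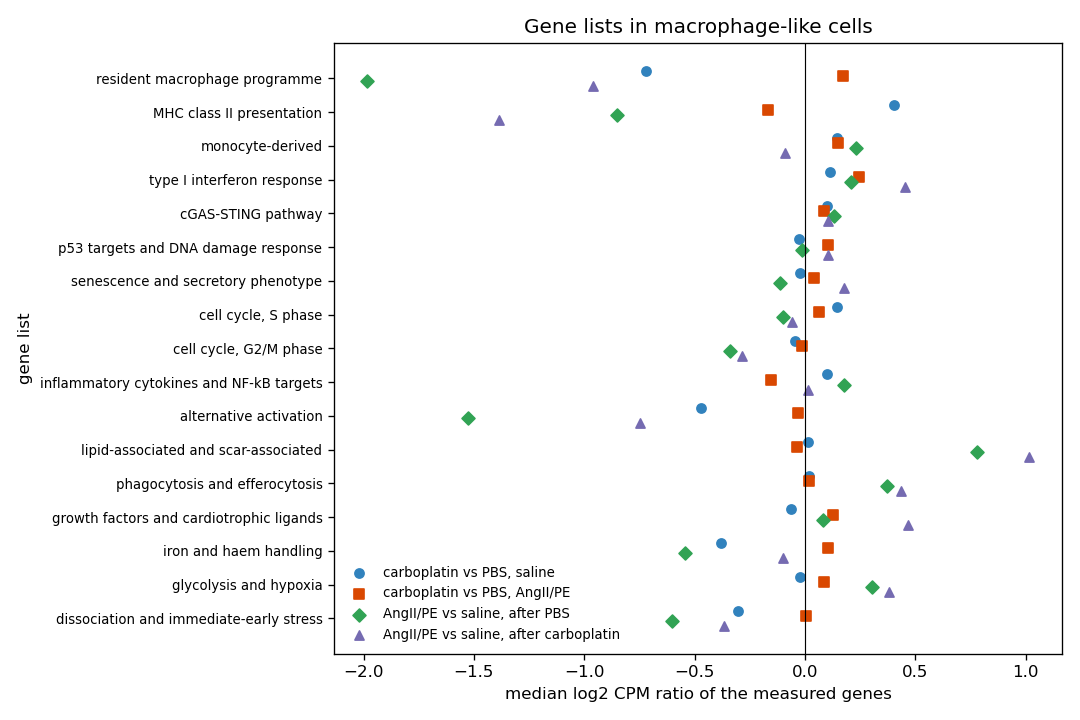
Median log2 CPM ratio (x axis) of the measured genes of each list (y axis) in macrophage-like cells, 1 symbol per contrast. The AngII/PE contrasts spread from -1.98 to 1.01 and the carboplatin contrast under AngII/PE from -0.17 to 0.25. The sex-linked list is not drawn.

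Set side by side, the carboplatin contrasts, which share no library, had 24 genes at least 2-fold lower in both, where independent lists would share 0.255. These included Timd4, not told apart from background in the AngII/PE libraries, Cd163, Vsig4, Colec12, P3h2, Hs3st3a1 and Celf4. Others, named after their values were seen, were the thyroid hormone receptor Thrb (-2.45 and -2.27), the phospholipase Pla2g2d (-2.57 and -4.71, the latter from 5 and 75 UMIs) and the B cell chemokine Cxcl13 (-1.50 and -3.12). Ly6a, also named after its values were seen, was the gene at least 2-fold higher in both (1.21 and 1.33), and none had opposite directions. Across all 8493 genes, which are not independent replicates, the correlation was r = 0.276 (Spearman's coefficient -0.004).

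Among genes with a mean of at least 20 CPM, the difference of the log2 ratios, AngII/PE minus saline, was largest upward for Cd207 (5.56), Retnla (2.87), Colec12 (2.07), Cd163 (2.04) and Ccl24 (1.94), and downward for Cacna1a (-2.12), Mmp12 (-1.90), Ccl5 (-1.73), Nlrp1b (-1.59) and Kcnn4 (-1.43). For lists, the median difference was 0.75 in the resident programme, with 10 of 14 genes at least 1.5-fold up and 1 down, and -0.58 in MHC class II presentation, with 5 of 10 down. It was 0.46 for alternative activation, 0.36 for iron handling, 0.28 for immediate-early and -0.28 for inflammatory genes. In female- and male-called cells it was 1.14 and 0.66 for the resident programme, -0.45 and -1.08 for MHC class II presentation, 0.89 and 0.42 for alternative activation, 0.34 and 0.41 for iron handling, 0.09 and 0.46 for immediate-early and -0.26 and -0.07 for inflammatory genes. Within the resident-like cluster alone these were -0.12 for the resident programme, 0.12 for MHC class II presentation and 0.16 for inflammatory genes. That cluster was named by the same genes as the resident programme list, and several of them are among its leading genes. A small value for this list there may therefore be partly built in. None of these differences was tested.

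**Figure D3:**
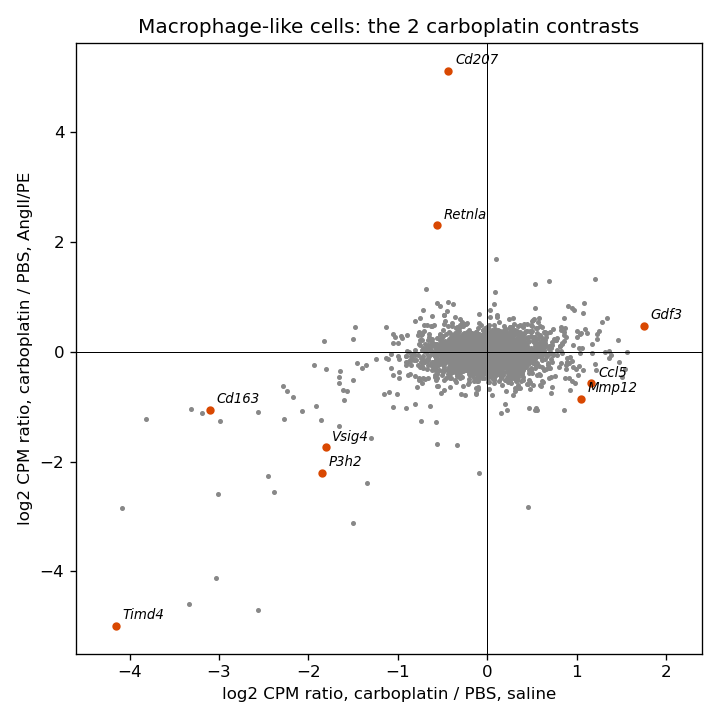
Log2 CPM ratio of carboplatin to PBS in macrophage-like cells under saline (x axis) and under AngII/PE (y axis), 1 point per gene with a mean of at least 10 CPM. Timd4 lies lowest, at -4.15 and -4.99, the latter between levels not told apart from background, and Cd207 highest on the y axis, at 5.13.

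The third comparison asked what AngII/PE changed after PBS. Genes of resident macrophages and of alternative activation were lower under AngII/PE: Retnla 834-fold (466 to 1672, a ratio to 11 UMIs with no background measured), Timd4 28.4-fold, Ccl24 13.8-fold (12.6 to 15.1), Lyve1 12.5-fold and Colec12 10.5-fold (9.69 to 11.3). The folds of Timd4 and Lyve1 are point estimates. They may be too small, since the AngII/PE shares of cells with these genes were not told apart from those of endothelial-like cells. Genes of lipid- and scar-associated macrophages were higher: the matrix protein osteopontin, Spp1, 8.08-fold (7.58 to 8.63), the collagenase Mmp14 7.03-fold (6.38 to 7.77), the lysosomal glycoprotein Gpnmb 6.36-fold (5.58 to 7.28) and the apolipoprotein Apoc2 6.26-fold (5.51 to 7.15). Ccl5 was 6.74-fold higher (5.96 to 7.63) and Ms4a7 5.24-fold (5.12 to 5.35). The resident-like cluster held 91.1% of the saline cells and 4.12% of the AngII/PE cells, so these values compare different clusters. Female-called cells were 29.2% of called macrophage-like cells under AngII/PE and 44.9% under saline.

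Of the 8493 genes, 241 were at least 2-fold higher and 295 at least 2-fold lower under AngII/PE, with the same direction in both sexes for 241 and 294. Across 8489 genes not chosen by fold, the female and male log2 ratios had r = 0.769 (Spearman's coefficient 0.638). Male-called cells alone gave 374 higher, and the resident-like cluster alone 97 higher and 164 lower. Also at the low end were Cd207 (-8.22), the calcineurin homologue Chp2 (-5.08), Celf4 (-3.98), P3h2 (-3.41), Cmah (-3.34), the histamine receptor Hrh1 (-3.28) and lysozyme Lyz1 (-3.07). At the high end were Syngr1 (4.23), Arhgap24 (3.99), Dock5 (2.88), Kcnn4 (2.82), the receptor anchoring protein Rapsn (2.60) and Tmem119 (2.55), known from microglia. Spp1 was higher by a log2 ratio of 1.31 in female-called and 4.48 in male-called cells, and Gpnmb by 1.14 and 3.81. Spp1 lies on chromosome 5 (104435118 to 104441050, plus strand) and Lyve1 on chromosome 7 (110850607 to 110863239, minus).

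In the lipid-associated list 16 of 25 genes were at least 1.5-fold higher and 2 lower (median 0.78), above all random lists, with thrombospondin Thbs1 at 3.07. In the resident programme 13 of 14 were lower (-1.98) and in alternative activation 7 of 10, with 1 higher (-1.53). In MHC class II presentation 8 of 10 were lower and 1 higher (-0.85), with H2-Aa at -0.94, and in iron handling 7 of 14 (-0.54), including the transferrin receptor Tfrc (-2.95). Interferon genes were higher for 8 of 34 (0.21), with Irf7 at 1.80, and inflammatory genes for 9 of 28 and lower for 1 (0.18, but -0.03 in male-called cells), with Ccrl2 at 1.79. Phagocytosis genes had 9 of 27 higher and 6 lower (0.37), with Cd300lf at 3.49 and Cd36 at -2.29, and growth factors 6 of 15 higher and 2 lower (0.08), with Gdf3 at 2.09 and Gdf15 at 1.69. Glycolysis genes stood at 0.30, monocyte-derived genes at 0.23 (-0.12 in female-called cells), cGAS-STING at 0.13, p53 targets at -0.01, senescence at -0.11, S phase at -0.10 and G2/M at -0.34, the last at 0.29 with a minimum of 1 CPM. Immediate-early genes had 17 of 33 lower (-0.60), with the heat shock gene Hsph1 at -2.26. Markers of other cell types moved too: cardiomyocyte markers stood at -1.07 over 7 genes and fibroblast markers at 0.97 over 3, with Mgp at 2.14. Classical monocyte markers stood at 0.68 over 7 genes and cDC2 markers at -0.40 over 5. Sex-linked genes had a median of 0.70, with Ddx3y at 0.81 and Xist at -0.61. Within the resident-like cluster alone the medians were 0.07 for the resident programme, -0.17 for interferon genes and 0.11 for iron handling. Within the MHC class II cluster they were -0.50 for interferon, -0.02 for lipid-associated and -0.62 for glycolysis genes. The resident-like cluster was named by the resident programme genes, so the small value of that list there may be partly built in.

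The last comparison set AngII/PE against saline after carboplatin. Lower under AngII/PE were Retnla, 114-fold (92.8 to 141, a ratio to 95 UMIs with no background measured), and the lectin Mgl2, 8.87-fold (8.56 to 9.20). Lyve1 was 6.52-fold lower. This point estimate may be too small, since the AngII/PE share of cells with Lyve1 was not told apart from that of endothelial-like cells. Timd4 had 7 UMIs under AngII/PE and 108 under saline, where its share of cells lay close to the limit of background, so no fold is read. Spp1 was 8.01-fold higher (7.46 to 8.61), the lysosomal protease Ctsd 5.82-fold (5.65 to 6.01), the lipid receptor Trem2 4.72-fold (4.53 to 4.92), Ms4a7 4.93-fold (4.81 to 5.06) and the glucocorticoid-induced Fkbp5 4.78-fold (4.37 to 5.24). The resident-like cluster held 82.5% of the saline cells and 1.15% of the AngII/PE cells.

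Here 164 genes were at least 2-fold higher and 244 at least 2-fold lower, with the same direction in both sexes for 163 and 243. Across 8489 genes not chosen by fold, the female and male log2 ratios had r = 0.850 (Spearman's coefficient 0.817). Other low-end genes were Cacna1a (-5.16), Celf4 (-3.93), P3h2 (-3.76), Chp2 (-3.50), Hs3st3a1 (-3.17), Hrh1 (-2.88), Lyz1 (-2.74) and Cd207 (-2.66). Other high-end genes were Syngr1 (3.60), Arhgap24 (3.08), Rapsn (2.62), Tmem119 (2.32), Dbp (2.15), Apoc2 (1.996) and the tetraspanin Tspan4 (1.98). The AngII/PE contrasts, which share no library, had r = 0.857 (Spearman's coefficient 0.819) across genes, but 0.289 within the resident-like cluster, with 131 genes higher and 185 lower in both, where independent lists would share 4.65 and 8.48.

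The lipid-associated list had 15 of 25 genes higher and 2 lower (median 1.01). MHC class II presentation had 7 of 10 lower (-1.39), with Ciita at -1.88 and H2-Ab1 at -1.75, the resident programme 8 of 14 lower and 1 higher (-0.96) and alternative activation 5 of 10 lower and 1 higher (-0.75), with Chil3 at 3.07. Interferon genes were higher for 14 of 34 (0.45), with Irf7 at 1.77 and Ifit3b at 1.50, but the median was 0.76 in female- and 0.08 in male-called cells. Growth factors were higher for 6 of 15 and lower for 1 (0.47), with progranulin, Grn, at 1.31, and phagocytosis genes were higher for 10 of 27 and lower for 4 (0.44). Glycolysis genes stood at 0.38, inflammatory genes at 0.01, iron handling at -0.10, monocyte-derived genes at -0.09, cGAS-STING at 0.11, p53 targets at 0.11, senescence at 0.18, S phase at -0.06, G2/M at -0.29 (0.02 with a minimum of 1 CPM) and immediate-early genes at -0.37. Cardiomyocyte markers stood at -0.92, fibroblast markers at 0.83, cDC2 markers at -0.54, classical monocyte markers at -0.18 and sex-linked genes at 0.20. Within the MHC class II cluster alone, the 1 cluster with at least 50 cells in every library, the resident programme stood at 0.74, interferon genes at -0.11 and glycolysis genes at -0.02. Fewer than 3 markers of endothelial, mural, erythroid, B, T and neutrophil cells were measured in macrophage-like cells, so no median is given for these.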

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

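The tests of explanations in the 3 patterns weighed here were chosen only after the result was seen. The carboplatin contrast had opposite signs under saline and under AngII/PE for several results in macrophage-like cells. The list medians were -0.72 and 0.17 for the resident macrophage programme (a difference of medians of 0.89), 0.40 and -0.17 for MHC class II presentation (-0.57), 0.10 and -0.16 for inflammatory cytokines (-0.25; in male-called cells -0.11 and -0.20, the same sign) and -0.38 and 0.10 for iron and haem handling (0.49). The log2 ratio of Mmp12 was 1.04 and -0.85 (-1.90), but 1.82 and 0.42 in female-called cells, the same sign. The macrophage-like share ratio was 0.926 and 1.03, a quotient of 1.11, and the dendritic-cell-like share ratio 1.28 and 0.439, a quotient of 0.342. Clustered without marker genes, the macrophage-like ratio under AngII/PE was 1.01 (0.986 to 1.03), and with log-normalised values or with the unnamed clusters included the dendritic-cell-like ratio under saline was 1.02. These ratios stayed on the same side of 1, but their intervals held 1, so the opposite signs are not clear under each setting. The Cd207 ratio under AngII/PE was 7.35 in female-called and -1.27 in male-called cells, a difference of 8.63. These rest on 483 UMIs after carboplatin against 1 after PBS in female-called and 3 against 6 in male-called cells, with intervals of 4.87 to 12.66 and -3.90 to 0.95 for counting error, which treat UMIs of 1 cell as independent, so neither the fold nor the difference is measured closely. For all of these the difference was not tested, since each group is 1 library. Endothelial-like cells, which the comparisons of macrophages leave out, had AngII/PE to saline ratios after PBS of 4.15 for Plvap and 5.59 for Lrg1 on the log2 scale, with 4.74 and 5.38 after carboplatin.

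The first pattern weighed is the set of 24 genes at least 2-fold lower in both carboplatin libraries, Cd163 and Vsig4 among them. Different shares of female and male cells are argued against, since the highest median of these genes within a sex was -1.78. Fewer cells of the resident-like cluster are argued against as the whole cause, since within that cluster the median was -2.41 under saline and -3.29 under AngII/PE, the latter from 45 and 88 cells. Under saline this outcome was nearly fixed. The cluster held 91.1% of macrophage-like cells after PBS and 82.5% after carboplatin, too small a fall for a 2-fold loss. The 24 genes were chosen from sums of the same cells, so none of these medians, within a sex or the cluster, is an independent test. The loss of a part of that cluster and lower expression in each cell both stay open and were not tested. An effect of carboplatin is a hypothesis that a single library per group leaves untested.

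The second pattern is Cd207, 34.9-fold higher in the carboplatin AngII/PE library, as a ratio to 8 UMIs. The dendritic-cell-like cells of that library had 0 Cd207 UMIs, which allows up to 1.91 CPM, against 8.62 CPM in macrophage-like cells. That bound treats UMIs as independent, although 1 cell held 361. A class mean cannot tell of a few dendritic cells placed among macrophage-like cells, so that explanation stays open. Cells or RNA carried over from a saline library cannot be told apart from cells of this library, since the 4 resident-like cells with Cd207 held 0 Cd163 UMIs, and so did 17.3% of draws of 4 such cells from the carboplatin saline library and 2.49% from the PBS saline library. A few cells of female animals may be the source, since the interval of the male-called value of -1.27 ends below 1, but that value rests on 3 and 6 UMIs in few cells, so other sources stay open. Of 487 UMIs, 415 lay in these 4 cells and 361 in 1 of them, and whether these came from 1 mouse was not tested.

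The third pattern is the opposite sign of the resident programme median in the carboplatin contrasts. Different shares of female and male cells are argued against, since the difference of the medians was 0.97 in male-called and 1.10 in female-called cells. For a different mix of macrophage-like clusters the tables disagree. That difference was 1.40 (0.82 to 1.64) within the MHC class II cluster, with 10 of the 14 genes above the floor. It was -0.06 (-0.21 to 0.05) within the resident-like cluster, with 13 of 14. The resident-like cluster was named by these same genes, so the small value there may be partly built in. A mix of clusters and a change within clusters therefore cannot be told apart for these genes. The difference of the medians was large within 1 of these clusters, and its interval spanned both signs within the other. The MHC class II cluster held 84 cells for PBS with saline and 96 for carboplatin with saline. Whether the medians themselves had opposite signs within a cluster was not checked.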

How the results depend on the processing

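Alternatives that left out the tenth of cells with the highest Scrublet scores, counted the unnamed macrophage-marker clusters as macrophage-like, left out cells with UMIs of both sexes or gave every library 1013 cells were chosen only after seeing the data; the others were planned. No paired analysis was possible because each group is 1 library, so that the groups share only the replicate number 1 and no result comes from a test. Of share ratios, 156 stayed within their counting interval, 56 moved beyond it and 4 reversed, which is said of a ratio that crossed 1 where its counting interval had excluded 1. Another 4 crossed 1 from an interval that held it. The share ratios under a 5% mitochondrial limit, a resolution of 0.3 and without Scrublet doublets all stayed. Leaving out Scrublet doublets removed only 49 cells, so that setting could change little. Gene counts stayed within 1.5 times in 91 cases and moved in 29, which does not say that the genes were shared. Correlations between contrasts stayed in 2 cases, both with TMM factors, and moved in 6. TMM factors shift all log2 ratios of a contrast alike, so they could hardly change a correlation. Counts of lists with a median beyond 0.2 from 0, which leave out the sex-linked list, stayed in 64 cases and moved in 11. List medians stayed in 791 cases, moved in 469 and reversed in 15, which is said of a median at least 0.2 from 0 and outside the central 95% of random lists that changed sign. Another 148 medians that missed either limit changed sign, so that 163 did so in all, 17 of them in female-called and 18 in male-called cells. Marker shares stayed in 12 cases and moved in 96, while the number of markers with separate intervals stayed in all 12. Monocyte-like ratios had no value within a sex in 4 cases, where a library had no such cell. In what follows, carboplatin ratios are against PBS and AngII/PE ratios against saline, the value under the settings of the report stands in parentheses, and the cause was not tested unless stated.

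Clustered without marker genes, the macrophage-like ratio was 1.01 (1.03) for carboplatin under AngII/PE, reversed to 0.965 (1.04) for AngII/PE after PBS and was 1.07 (1.16) after carboplatin. The resident-like ratio was 0.462 (0.288) for carboplatin under AngII/PE, and 0.0932 (0.0470) and 0.0514 (0.0161) for AngII/PE after PBS and after carboplatin. For these AngII/PE ratios, the dendritic-cell-like values were 0.935 (0.746) and 0.360 (0.255) and the cycling values 3.59 (1.38) and 2.35 (1.09). With log-normalised values and 30 components, the macrophage-like ratio was 0.966 (0.926) for carboplatin under saline, and 1.01 (1.04) and 1.08 (1.16) for AngII/PE after PBS and after carboplatin. The resident-like ratio was 0.457 (0.839) for carboplatin under saline, reversed to 1.30 (0.288) under AngII/PE, and was 0.153 (0.0470) and 0.435 (0.0161) for AngII/PE. The dendritic-cell-like ratio was 1.02 (1.28) for carboplatin under saline, reversed to 1.03 (0.746) for AngII/PE after PBS and was 0.470 (0.255) after carboplatin.

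At a resolution of 1.2, the macrophage-like ratio was 0.762 (0.926) for carboplatin under saline and 1.19 (1.04) and 1.61 (1.16) for AngII/PE after PBS and after carboplatin. The resident-like ratio was 0.537 (0.839) and 0.172 (0.288) for carboplatin under saline and under AngII/PE, and 0.0302 (0.0470) and 0.00968 (0.0161) for AngII/PE. For AngII/PE, the dendritic-cell-like ratios were 0.447 (0.746) and 0.154 (0.255) and the cycling ratios 0.816 (1.38) and 0.544 (1.09). With more than 1000 genes per cell, the resident-like ratio reversed to 1.01 (0.288) for carboplatin under AngII/PE and was 0.102 (0.0470) and 0.121 (0.0161) for AngII/PE. Without the tenth of cells with the highest Scrublet scores, the macrophage-like ratio was 0.963 (0.926) for carboplatin under saline and 1.02 (1.04) and 1.09 (1.16) for AngII/PE. The resident-like ratio was 0.671 (0.839) for carboplatin under saline, and the dendritic-cell-like ratios were 0.935 (0.746) and 0.362 (0.255) for AngII/PE. With the unnamed clusters included, the macrophage-like ratios were 0.981 (0.926), 1.01 (1.03), 1.02 (1.04) and 1.05 (1.16) for carboplatin under saline, under AngII/PE, and AngII/PE after PBS and after carboplatin. The resident-like ratio was 0.666 (0.839) for carboplatin under saline and 0.0256 (0.0161) for AngII/PE after carboplatin, the dendritic-cell-like ratio 1.02 (1.28) and 0.405 (0.255) for the same, and the cycling ratio 1.73 (1.09) for AngII/PE after carboplatin. For these classes the unnamed clusters entered only the total of phagocytes. No unnamed cell was counted as resident-like, so the resident-like values do not say how many of them were.

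In female-called cells, the macrophage-like ratio was 1.06 (1.04) for AngII/PE after PBS, the resident-like ratio 0.537 (0.288) for carboplatin under AngII/PE and 0.0322 (0.0161) for AngII/PE after carboplatin, and the cycling ratio 1.17 (2.03) for carboplatin under saline and 0.674 (1.38) for AngII/PE after PBS. There 24 (8) genes were higher after carboplatin under AngII/PE with 4 (1) lists beyond 0.2, and the correlations were 0.234 (0.276) for the carboplatin and 0.806 (0.857) for the AngII/PE contrasts. In male-called cells, the corresponding ratios were 1.01 (1.04), 0.0930 (0.288), 0.00506 (0.0161), 6.84 (2.03) and 3.91 (1.38), and the monocyte-like ratio for carboplatin under saline was 3.61 (2.42). There 139 (36) genes were higher and 131 (57) lower after carboplatin under saline, 3 (8) higher after carboplatin under AngII/PE with 2 (1) lists beyond 0.2, and 374 (241) higher under AngII/PE after PBS, with correlations of 0.133 (0.276) and 0.730 (0.857).

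A minimum of 1 CPM in place of 10 admits more genes, and gave 181 higher and 265 lower for carboplatin under saline, 29 and 154 under AngII/PE, 621 and 802 for AngII/PE after PBS and 406 and 717 after carboplatin. A minimum of 50 CPM admits fewer and gave 5 and 10, 3 and 8, 80 and 118, and 55 and 90 in that order. For carboplatin under AngII/PE, lists beyond 0.2 were 2 (1) with 1 CPM, 3 with 50 CPM, 3 with TMM factors, 3 with equal cell numbers and 2 with mean CPM of cells. With 1 CPM, the G2/M median reversed to 0.29 (-0.34) for AngII/PE after PBS and 0.025 (-0.29) after carboplatin.

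Equal cluster weights used the MHC class II cluster alone, the 1 with at least 50 cells in every library. They gave 160 (36) genes higher and 155 (57) lower for carboplatin under saline, from 96 and 84 cells, and 15 (8) and 18 (38) under AngII/PE. For AngII/PE the counts stayed within 1.5 times, but only 67 of 317 (241) higher and 66 of 300 (295) lower genes after PBS, and 65 of 181 (164) and 63 of 205 (244) after carboplatin, were among those of the report. Lists beyond 0.2 were 2 (1) for carboplatin under AngII/PE and 10 (6) for the difference. Medians reversed to -0.50 (0.21) for interferon, -0.025 (0.78) for lipid-associated and -0.62 (0.30) for glycolysis genes for AngII/PE after PBS, and to 0.74 (-0.96) for the resident programme, -0.11 (0.45) for interferon and -0.020 (0.38) for glycolysis genes after carboplatin. In the resident-like cluster alone, with 45 and 88 cells under AngII/PE, 224 (8) genes were higher and 438 (38) lower for carboplatin under AngII/PE, with 10 (1) lists beyond 0.2, and 97 (241) higher and 164 (295) lower for AngII/PE after PBS, with 5 (11). Here 21 of 38 (36) higher and 51 of 67 (57) lower genes for carboplatin under saline, and 42 of 157 (164) and 67 of 355 (244) for AngII/PE after carboplatin, were among those of the report. The correlations were 0.332 (0.276) for the carboplatin and 0.289 (0.857) for the AngII/PE contrasts. Medians reversed to 0.069 (-1.98) for the resident programme, -0.17 (0.21) for interferon and 0.11 (-0.54) for iron genes for AngII/PE after PBS, and to 0.039 (-0.29) for G2/M after carboplatin. The median differences between the carboplatin contrasts reversed to -0.12 (0.75) for the resident programme, 0.12 (-0.58) for MHC class II and 0.16 (-0.28) for inflammatory genes. The resident programme genes also named this cluster, so the small values of that list here may be partly built in.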

Other observations

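None of the genes named here was chosen before its values were seen, and no test was run. Endothelial-like cells, which entered the sorted libraries at 598 cells for PBS with saline, 554 for carboplatin with saline, 304 for PBS with AngII/PE and 355 for carboplatin with AngII/PE, differed between saline and AngII/PE. Of 7251 genes compared, 202 were at least 2-fold higher and 161 lower under AngII/PE after PBS, and 190 and 113 after carboplatin. Lrg1, a secreted glycoprotein of activated endothelium, stood at 2.17 CPM for PBS with saline, 1.46 for carboplatin with saline, 104 for PBS with AngII/PE and 61.0 for carboplatin with AngII/PE. Plvap, a component of endothelial diaphragms, stood at 7.96, 2.92, 142 and 78.3 CPM in the same order. Von Willebrand factor, Vwf, had log2 ratios of 1.33 after PBS and 0.81 after carboplatin. For carboplatin against PBS, 26 genes were higher and 50 lower under saline, and 22 and 14 under AngII/PE. Under AngII/PE, the interferon-induced Cxcl9 had a carboplatin to PBS log2 ratio of 1.42 and Isg15 1.13. Cxcl10 had 4.11, but its CPM was higher in macrophage-like than in endothelial-like cells, so RNA from other cells stays open for it.

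Values in macrophage-like cells are given for 4 genes known from the circadian clock, picked by hand and not from a fixed list. The log2 ratio of Dbp was -0.57 for carboplatin under saline, 0.90 under AngII/PE, 0.69 for AngII/PE after PBS and 2.15 after carboplatin. In the same order, the values were -0.81, 0.57, 0.17 and 1.55 for the nuclear receptor Nr1d1, -0.49, 0.29, 0.52 and 1.29 for Tef, and -0.16, -0.32, -1.55 and -1.72 for Arntl, the clock's activating factor. The hour at which each group's hearts were collected is not given in the sources used here.

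A cluster without a name, with Csmd1, Cadm2 and Kcna1 among its leading genes, held 136 cells, of which 112 came from the carboplatin saline library, 12 from PBS with saline, 9 from PBS with AngII/PE and 3 from carboplatin with AngII/PE. With 1 library per group, a state of the hearts and the preparation of that library were not separated. Cells with UMIs of both Xist and Y-linked genes were 3.55%, 5.17%, 5.59% and 8.42% of cells with a sex-linked UMI for PBS with saline, carboplatin with saline, PBS with AngII/PE and carboplatin with AngII/PE.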
